A study of Homo sapiens with 32 samples.

How the data were processed

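The series held 32 samples of Jurkat cells, of which 6 were RNA-seq, 6 ATAC-seq and 20 ChIP-seq. Only the table of RNA values was used, and the other samples are not analysed here. Groups were taken from the labels: 3 lines (wild type, ZBTB1 knockout, and knockout carrying a ZBTB1 cDNA), each with and without asparagine, with 1 library per group. The labels give no length of withdrawal for the RNA samples.

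The authors deposited 1 table of TPM (transcript abundance scaled to a fixed total per library) per gene and library, per the file headers, with 2 decimals. Per the labels' protocols, RNA was isolated with a Qiagen RNeasy kit and libraries followed standard Illumina protocols. The submitters' processing notes name HOMER, featureCounts, edgeR, hg19 and GRCh37 for the series with no role for each. The aligner, the quantifier and the use of strand behind the TPM table are not given in the sources used here. Another 3 value columns (length, effective length and expected count) carry no library name and were not used. TPM keeps no depth, so the counting error of each value is unknown, low values are less certain than high ones, and a gene listed at 0 may be a failed estimate. No TPM ratio is given against a value of 0, and the size of a log2(TPM + 1) difference that involves 0 is set by the pseudocount.

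The table had 56429 lines for 56426 gene identifiers, and 3 lines repeating an identifier were left out. Symbols came from the table for 36775 genes and from a reference of gene names for 4338, with 56104 identifiers present in that reference. No coordinates are given. Genomic gene length, used in 1 check only, came from RefSeq genes of assembly GRCh38.p14, matched by name for 13210 genes (92.2%). Values between any pair of libraries were identical for at most 0.517% of genes, so no library appeared to be deposited more than once.

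Values were compared as log2(TPM + 1), which understates the change of low genes, over 14326 genes with a mean of at least 1 TPM. The change on withdrawal was the difference without minus with asparagine within a line. With 1 library per group, genes were counted at a difference of at least 2-fold with no p-value. Differences of the knockout-labelled line were counted where they reached 2-fold in the same direction against wild type and against the cDNA line. Since both use the same library, 100 simulations of unchanged lines gave an overlap from sharing. Their spread was taken from differences between lines, which may include real ones, so this overlap can be too high. They hold no shift of all genes. The same simulation for the difference of responses was added after the results were seen.

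The average response over lines was tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with line as a block, medium as the effect and a trended prior variance, giving 2 residual degrees of freedom. Calls used a Benjamini-Hochberg adjusted p below 0.05. All adjusted p-values in the text are from this test. Nothing says that the libraries of a line came from separate experiments, so the p-values measure the spread between these 3 lines. The cDNA line derives from the knockout line, so the 3 lines are not independent, and the test does not allow for this. On simulated data with 200 changed genes among 14326, the test recovered 56% of genes changed 1.5-fold, 88% at 2-fold, 92% at 3-fold and 100% at 4-fold. It called 17 of 14126 unchanged genes, 9.19% of its calls, which is above the nominal rate. The simulated noise was independent and normal, and its spread depended on expression alone, with no scatter between genes of like expression. Such noise favours a trended prior, so these rates may be too favourable for the real data.

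For each of 25 gene lists, the median difference was placed among 10000 random lists of the same size drawn from 20 expression bins. In a simulated check of lists of 20 genes, 20 of 20 lists shifted by 0.4 were found and 1 of 20 unshifted lists was. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

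Before the data were examined, the groups, tests, lists, alternatives and the rule for named genes were fixed. The text names ZBTB1 and ASNS. Among genes with a mean of at least 5 TPM it names the 10 up and 10 down with the largest smallest response of 1 sign over the 3 lines. It names the 8 and 8 with the largest smaller difference of the knockout-labelled line from both others in each medium, and the same number for the difference of responses. From each list up to 4 measured members with the largest absolute values could be named, and other names are said to be chosen afterwards. A few genes that these rules would name are not reported here.

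Alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 10 TPM, thresholds of 1.5-fold and 3-fold, and lines of the same symbol summed. Scaling alternatives were median-of-ratios over genes with a mean of at least 10 TPM, and TPM rescaled without mitochondrial, ribosomal protein, histone and small noncoding RNA genes. For limma they were no block, a constant or robust prior, each line left out, and a 2-fold threshold added. Leaving out any line lowers the residual degrees of freedom, so calls can be lost with no loss of fold. Counts per list were made only without the knockout-labelled line.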

Results

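Jurkat cells, an established human T-cell leukaemia line, were grown with or without asparagine, an amino acid that asparagine synthetase (ASNS) makes from aspartate. The study set the parental wild-type line beside a ZBTB1 knockout line and the knockout line carrying a ZBTB1 cDNA (the cDNA line). ZBTB1 encodes a zinc finger protein of the BTB family. RNA was sequenced from 6 libraries, 1 for each of the 3 lines in each of the 2 media, so no group had replicates. The values were TPM, which scale each library to the same total and keep no record of sequencing depth, so no counting interval is given. Of 56426 genes, 14326 had a mean of at least 1 TPM and entered the comparisons. Between 14162 and 14599 genes reached 1 TPM in each library. The 6 ATAC-seq and 20 ChIP-seq samples of the series are not analysed here.

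ZBTB1 (ENSG00000126804), the targeted gene, was not lower in the libraries labelled knockout than in wild type. With asparagine it stood at 42.62 TPM in wild type, 51.48 in the library labelled knockout and 68.78 in the cDNA line. Without asparagine the values were 36.64, 46.56 and 61.21 TPM. On the log2(TPM + 1) scale the knockout-labelled line lay 0.27 above wild type with asparagine and 0.34 without, about the spread of genes of like expression (1.01 and 1.04 robust SD). An edited gene can keep making RNA, so the transcript level does not check the knockout label, and the line is called knockout-labelled throughout. ZBTB1 did not pass the test for a change on withdrawal (limma, adjusted p = 0.225).

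ASNS (ENSG00000070669) had the lowest level in the knockout-labelled line in both media and an intermediate level in the cDNA line. With asparagine it stood at 130.84 TPM in wild type, 23.78 in the knockout-labelled line and 79.84 in the cDNA line. Without asparagine the values were 213.32, 56.02 and 130.06 TPM. Wild type was thus 5.50-fold above the knockout-labelled line with asparagine and 3.81-fold without, and the cDNA line was 3.36-fold and 2.32-fold above it. The cDNA line remained below wild type, which was 1.64-fold higher in each medium. Ranked over all 14326 genes by the smaller of the differences from the other lines, ASNS was number 11 of those lower in the knockout-labelled line with asparagine and number 35 without. Among the 3775 genes with a mean of at least 50 TPM, a limit chosen after the values were seen, it was number 1 and number 2.

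ASNS also rose on asparagine withdrawal, by 1.63-fold in wild type, 2.36-fold in the knockout-labelled line and 1.63-fold in the cDNA line. The mean log2 change was 0.87 (SE 0.12, 3 of 3 lines; limma, adjusted p = 0.0152). The response of the knockout-labelled line exceeded that of wild type by 0.50 and that of the cDNA line by 0.51. The median gene differed by 0.20 and 0.13 in those comparisons. With 1 library per group none of these differences between lines has a replicate check. The ASNS call depended on the form of the variance prior, with an adjusted p of 0.104 under a constant prior.

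**Figure D1:**
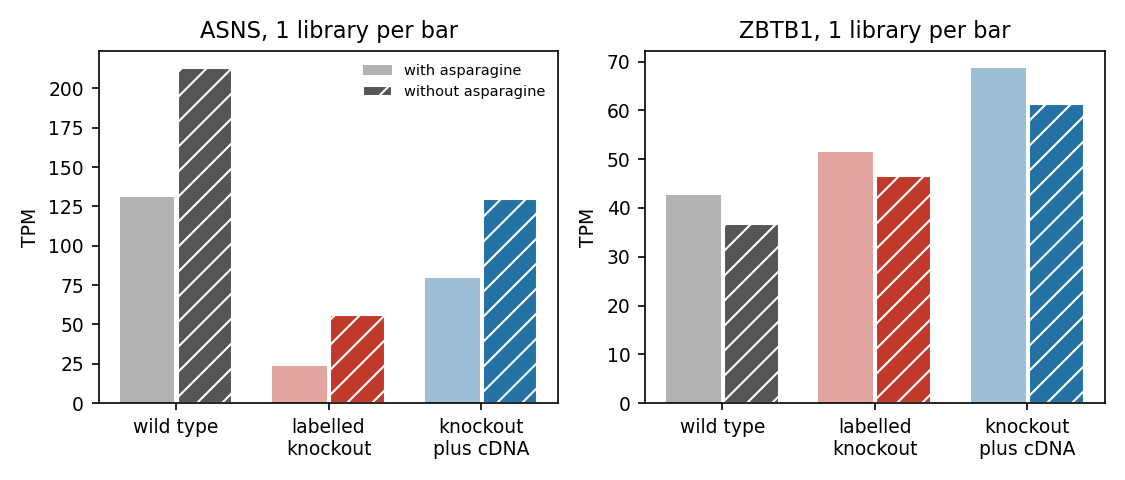
ASNS (left) and ZBTB1 (right) in TPM in each of the 6 RNA libraries, 1 library per bar with no error bars; plain bars are with asparagine and hatched bars without. ASNS ran from 23.78 TPM in the knockout-labelled line to 213.32 in wild type without asparagine, while ZBTB1 lay between 36.64 and 68.78 TPM.

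Asparagine withdrawal raised TRIB3, DDIT3 and TXNIP and lowered INSIG1, HMGCS1 and SCD in all 3 lines. TRIB3, a pseudokinase of the amino acid stress response, went from 59.86 to 315.31 TPM in wild type, 99.1 to 838.88 in the knockout-labelled line and 90.93 to 430.68 in the cDNA line. Its mean log2 change was 2.56 (SE 0.15, adjusted p = 0.00315). DDIT3, which encodes the transcription factor CHOP, rose by 1.27 (SE 0.10, adjusted p = 0.00392). TXNIP, the thioredoxin-interacting protein, and its relative ARRDC4 rose by 2.43 and 1.65 (adjusted p = 0.00383 and 0.0231). RGS16, a regulator of G-protein signalling, rose by 2.30 (adjusted p = 0.00657).

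INSIG1, which retains the sterol sensor complex in the endoplasmic reticulum, fell by 2.12 (SE 0.15, adjusted p = 0.00383). HMGCS1, the HMG-CoA synthase of the mevalonate pathway, fell by 2.40 (SE 0.29, adjusted p = 0.011). The stearoyl-CoA desaturase gene SCD went from 297.94 to 120.05 TPM in wild type, 361.65 to 99.94 in the knockout-labelled line and 352.31 to 145.92 in the cDNA line. The other genes with the largest shared increases were FAM129A, RGL4, BEST1, CCPG1 and the antisense gene NARF-AS2. Other large shared decreases were in DHCR7, MSMO1, LSS, CYP51A1, MVD and C6orf223, and all of these genes passed the test. NARF-AS2 is uncertain, since no source states that strand was used.

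Across all 14326 genes, 948 rose and 429 fell at an adjusted p below 0.05 in limma, with line as a block and the change averaged over the 3 lines. At an unadjusted p below 0.05 there were 4241, against 716 from chance alone. Under median-of-ratios scaling the counts were 878 and 734. The p-values rest on 3 lines that are not independent and on 2 residual degrees of freedom, and describe the spread between these lines. With a constant prior variance or without the filter on low values 0 genes passed. There were 7 without line as a block and 282 without the knockout-labelled line.

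**Figure D2:**
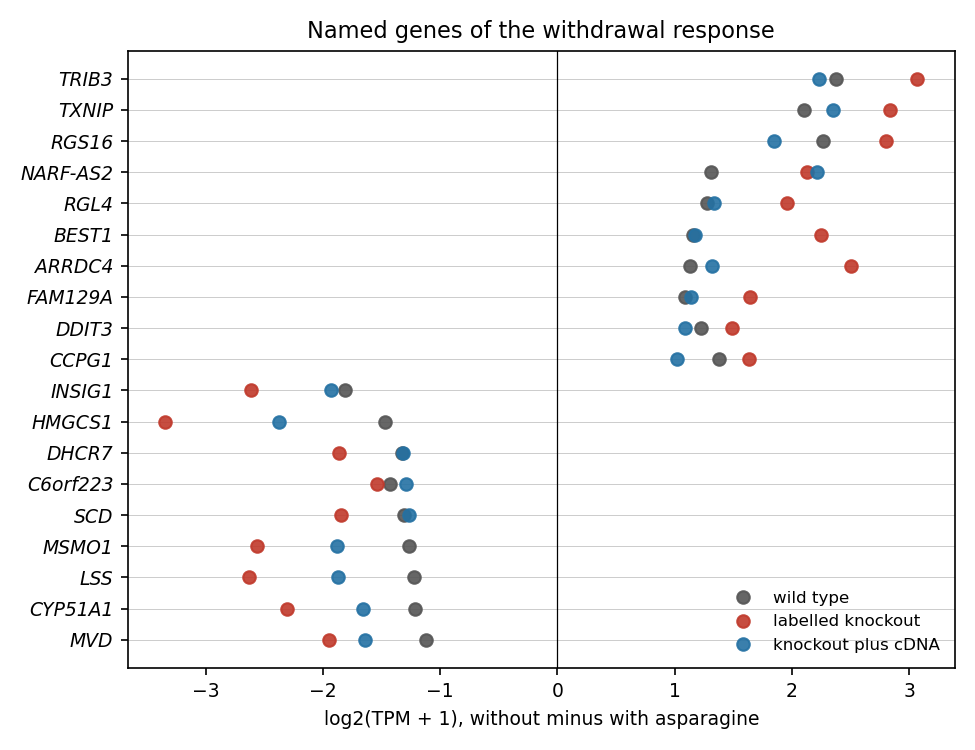
Change on asparagine withdrawal in log2(TPM + 1) for the 10 genes with the largest shared increase and 9 of the 10 with the largest shared decrease, 1 point per line and no error bars. Each gene shown moved the same way in all 3 lines, and the points ran from HMGCS1 at -3.34 to TRIB3 at 3.07, both in the knockout-labelled line.

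Among gene lists fixed in advance, the members of the ATF4 and amino acid lists that passed mostly rose, though many members did not pass. Of 23 measured genes described as ATF4 or CHOP targets, 10 rose, among them TRIB3, DDIT3 and FAM129A, and KLHL24 fell (-0.80). Adjusted over the list alone, 16 rose and 2 fell. ATF3 did not pass, with responses of 0.02, 2.27 and 0.91 in wild type, the knockout-labelled line and the cDNA line. Of 20 cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, 11 rose and none fell, led by WARS (0.93), FARSB (0.70), VARS (0.70) and SARS (0.53). Adjusted over the list alone, 14 rose and 1 fell. Of 11 genes that handle asparagine and aspartate, 4 rose, namely ASNS, ASNSD1 (0.53), GOT1 (0.52) and the asparaginyl-tRNA synthetase NARS (0.48), which is also in the synthetase list. Adjusted over the list alone, 7 rose.

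Of 14 amino acid carriers, SLC43A1 (0.87), the cystine carrier SLC7A11 (0.83), SLC7A1 (0.51), SLC1A4 (0.47) and SLC3A2 (0.43) rose and SLC38A2 (-0.54) fell. Adjusted over the list alone, 7 rose and 1 fell. Of 10 serine and one-carbon enzymes, MTHFD1L (0.77), PSPH (0.56) and SHMT2 (0.34) rose and 1 fell, with 4 risen and 1 fallen adjusted over the list alone. Of 14 other amino acid synthesis genes, 2 rose, including BCAT1 (0.42), and 5 rose adjusted over the list alone. SLC1A4, SLC3A2, NARS and KLHL24 were named after their values were seen. Without the knockout-labelled line, 9 ATF4 genes, 3 synthetases, 1 carrier and 1 asparagine-handling gene rose, while the median change of the carriers was 0.25 with or without that line and that of the synthetases went from 0.38 to 0.28. Under median-of-ratios scaling 10, 8, 5 and 4 of those lists rose. In the serine list 1 rose and 0 fell without that line (median change 0.19, from 0.15), and 2 rose and 1 fell under median-of-ratios scaling (median 0.07). In the list of other amino acid synthesis genes none passed without that line (median 0.13, from 0.22).

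All 21 measured cholesterol synthesis genes fell on asparagine withdrawal. Their mean log2 changes ran from -2.40 to -0.50, and 12 of the 21 were at least 2-fold lower in each of the 3 lines. HMGCS1 went from 122.39 to 43.47 TPM in wild type, from 306.42 to 29.3 in the knockout-labelled line and from 244.87 to 46.44 in the cDNA line. The lanosterol synthase gene LSS fell by 1.91 (adjusted p = 0.0109) and MSMO1 fell by 1.90 (adjusted p = 0.0102). The same 21 counted as fallen adjusted over the list alone, and 21 did under median-of-ratios scaling. Without the knockout-labelled line, 18 of the 21 passed the test as fallen (median change -1.25), while all 21 lay below 0 in both wild type and the cDNA line.

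Few genes of the proliferation lists passed. Of 20 S phase and replication genes, POLA1 (0.49), RRM2 (0.42), SLBP (0.32), TYMS (0.31) and MCM3 (0.29) rose, with 6 adjusted over the list alone, but only 1 rose under median-of-ratios scaling (median change 0.09, from 0.18) and 0 without the knockout-labelled line (median 0.19). Of 22 mitotic genes, the kinase gene TTK (-0.64) and CENPF (-0.43) fell, with 3 adjusted over the list alone, 3 under median-of-ratios scaling and 1 without the knockout-labelled line (median change -0.07 there, from -0.01). None of 12 replication-dependent histone genes passed, either way. Of 82 cytosolic ribosomal protein genes, RPL22L1 (0.76) rose and 7 fell, including RPS25 (-0.87) and RPS26 (-0.74). Adjusted over the list alone, 2 rose and 20 fell, while over all genes 2 of the 82 fell under median-of-ratios scaling and 1 without the knockout-labelled line. Their median change was -0.21, and -0.29 and -0.13 in those settings. Ribosomal proteins made up 13.0% of TPM in the knockout-labelled library without asparagine and between 15.3% and 18.2% in the other 5. Of 13 mitochondrially encoded genes, MT-ND3 (0.41) rose, also adjusted over the list alone, and none passed under median-of-ratios scaling or without the knockout-labelled line.

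In the stress and survival lists a few members passed, and most of these calls were lost without the knockout-labelled line, where 1 chaperone gene rose, 1 p53 target fell and no member of the other lists named here passed. The fit without it has fewer residual degrees of freedom, so a lost call alone does not show that this line carried the change. The median changes did not all shrink there, at 0.09 in both cases for the chaperones and from -0.07 to -0.14 for the autophagy list. That of the interferon list went from -0.04 to -0.15 and that of the apoptosis regulators from -0.14 to -0.12. The median of the p53 targets turned from 0.08 to -0.06. Of 17 endoplasmic reticulum chaperone genes, SEL1L (0.74) and HYOU1 (0.35) rose, and 1 did under median-of-ratios scaling. Of 15 p53 targets, BTG2 (-0.75) fell and AEN (0.61) rose. Of 16 apoptosis regulators, BMF (-0.70) and BID (-0.32) fell and PMAIP1 (0.45), which encodes NOXA, rose. Of 18 glycolysis and hypoxia genes, PFKFB4 (-0.97) and ALDOC (-0.86) fell while the hexokinase gene HK2 (0.63) and VEGFA (0.55) rose. Of 17 autophagy and lysosome genes, ULK1 (-0.60), GLA (-0.47) and NEU1 (-0.39) fell and ATG12 (0.38) rose, with 4 fallen and 1 risen adjusted over the list alone. Of 10 NRF2 targets, NQO1 (0.51) rose, with 2 up and 2 down adjusted over the list alone. Of 12 interferon-stimulated genes, ISG15 (-0.47) fell. Of 11 immediate early and activation genes, MYC (0.48) rose. For the chaperone, p53, apoptosis, glycolysis, interferon and immediate early lists the counts adjusted over the list alone were the same. Over all 14326 genes 1377 passed, so a few calls in a list do not by themselves show a response of that list. ATG12, like MCM3 among the replication genes, was named after its value was seen.

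Of 27 T-cell identity genes measured, the adaptor gene LAT (0.54) rose, and the count adjusted over the list alone was the same. The median response of the list was -0.12 in wild type, where 20 of 27 were below 0, and -0.01 in the cDNA line, while the 0.05 of the knockout-labelled line turned to -0.14 under median-of-ratios scaling. Markers of other cell types were mostly below the 1 TPM filter, with 2 of 7 B-cell, 2 of 10 myeloid, 2 of 8 erythroid and 3 of 10 epithelial and fibroblast genes measured. Of these, HBA1 (-0.58, adjusted p = 0.0468) and DCN (-0.87, adjusted p = 0.0475) fell, both also adjusted over their lists alone. No B-cell or myeloid marker passed, and without the knockout-labelled line no gene of these lists or of the T-cell list did.

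Line by line, the count of genes that differed after withdrawal was largest in the knockout-labelled line. At least 2-fold differences were counted for 116 genes higher and 141 lower in wild type, 741 and 193 in the knockout-labelled line, and 228 and 163 in the cDNA line. In all 3 lines, 21 genes were higher and 17 lower, a balance that turned to 19 and 21 under median-of-ratios scaling. Under median-of-ratios scaling the median response of all genes in the knockout-labelled line moved from 0.19 to 0.01, and its counts became 438 higher and 323 lower, with 198 and 192 in the cDNA line. Rescaling without ribosomal protein, mitochondrial, histone and small RNA genes gave 671 and 304. These counts come from single libraries and no test was made between lines.

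**Figure D3:**
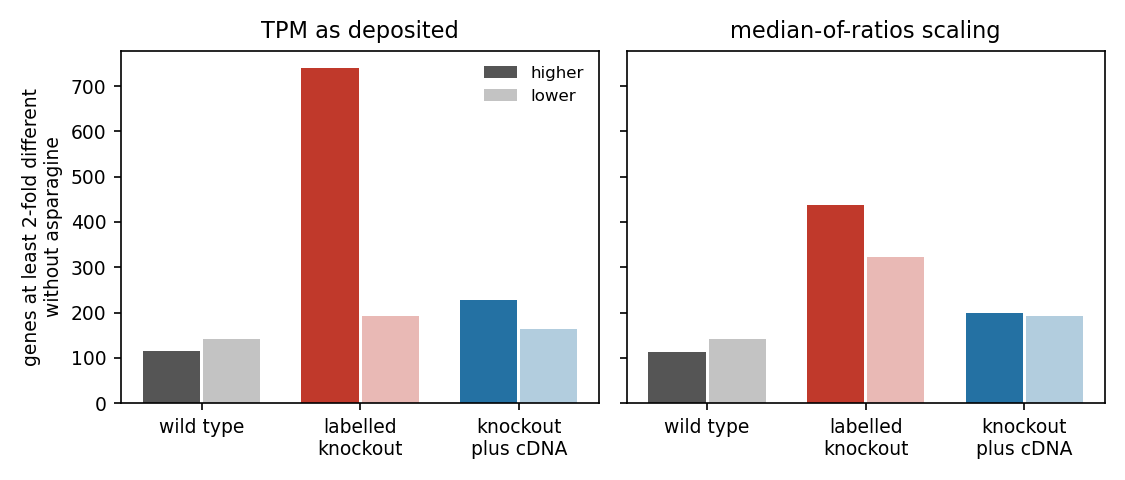
Number of genes at least 2-fold higher (dark) or lower (light) without than with asparagine in each line, from 1 library per medium, with TPM as deposited (left) and after median-of-ratios scaling (right). The knockout-labelled line had 741 higher and 193 lower as deposited, and 438 and 323 after rescaling.

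The cholesterol, ATF4, synthetase, asparagine and carrier lists each had medians of 1 sign in every line, largest in the knockout-labelled line. The median response of the 21 cholesterol genes was -1.03 in wild type, -1.84 in the knockout-labelled line and -1.32 in the cDNA line. Each of these lay below all 10000 random lists matched on expression. The ATF4 list had medians of 0.35, 0.80 and 0.39, each above all 10000 random lists. The synthetases, at 0.23, 0.57 and 0.31, also lay above all random lists in each line. Medians were 0.40, 0.68 and 0.32 for the asparagine list and 0.27, 0.50 and 0.24 for the amino acid carriers. With median-of-ratios scaling the knockout-labelled values were -2.03 for cholesterol, 0.61 for ATF4, 0.38 for synthetases, 0.49 for asparagine and 0.31 for carriers. Ribosomal protein genes had medians of -0.04, -0.38 and -0.22, and -0.57 in the knockout-labelled line under that scaling. Mitochondrially encoded genes had medians of 0.00, -0.20 and 0.31, and -0.40 in the knockout-labelled line under that scaling.

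**Figure D4:**
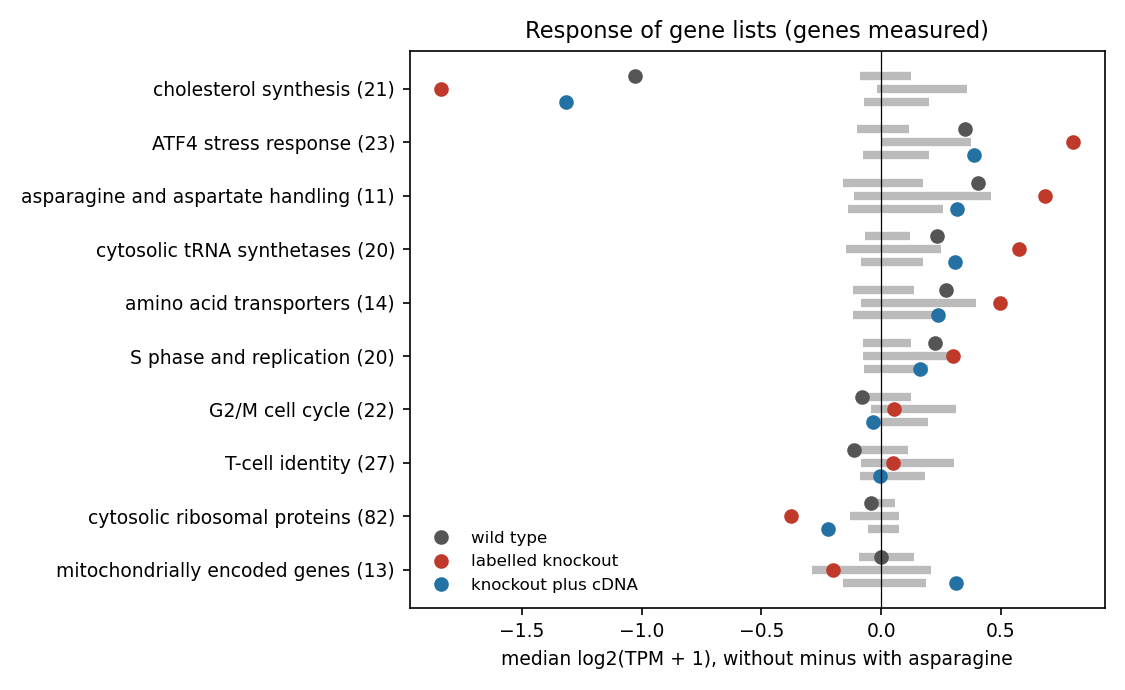
Median change on asparagine withdrawal in log2(TPM + 1) of 10 gene lists, 1 point per line, with the number of measured genes in brackets; grey bars span the central 95% of 10000 random lists matched on expression for the same line. Cholesterol genes lay at -1.03 to -1.84 in the 3 lines and ATF4 genes at 0.35 to 0.80; the small positive G2/M and T-cell values of the knockout-labelled line (both 0.05) became negative (both -0.14) under median-of-ratios scaling.

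With asparagine present, ASNS was among 45 genes at least 2-fold lower in the knockout-labelled library than in both wild type and the cDNA line, and 36 genes were higher. The balance turned to 62 lower and 102 higher without the filter on low values, and to 7 and 10 with a pseudocount of 5. ATP6V0A1, a subunit of the vacuolar proton pump, stood at 0.88 TPM against 23.48 in wild type and 7.49 in the cDNA line. The keratin gene KRT1 was at 2.84 against 13.44 and 7.33 TPM, SMKR1 at 2.66 against 10.02 and 7.05, and the T-cell receptor segment TRAV8-4 at 1.26 against 27.49 and 6.31. Genes higher in the knockout-labelled library included TSHR, the thyrotropin receptor, at 82.4 TPM against 31.09 and 38.85. EPSTI1 was at 25.55 against 3.54 and 9.79, ARHGAP33 at 77.14 against 28.23 and 33.28, GRIP1 at 16.06 against 6.28 and 3.77, and RHOBTB3 at 28.67 against 13.66 and 13.75. BTNL9, at 47.59 against 12.9 and 25.64, was also named by rank but fell short of 2-fold against the cDNA line. Pseudogenes and near copies that share sequence are uncertain, among them SEPT14P2, SEPT14P3, SNRPGP10 and PRSS2, and so is the antisense gene RNF185-AS1. SEPT14P3 stood at 17.77 TPM in the knockout-labelled library and was listed at 0 in both others, while SEPT14P2 was listed at 0 there and stood at 16.65 and 18.4 TPM in them.

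As groups, cholesterol genes were higher in both derived lines than in wild type with asparagine, by a median of 0.77 in the knockout-labelled line and 0.62 in the cDNA line. The knockout-labelled line exceeded the cDNA line by 0.14 for these genes. ATF4 genes likewise had medians of 0.42 and 0.41 above wild type, and differed by 0.11 between the derived lines. Mitotic genes were higher in the knockout-labelled line than in wild type by a median of 0.13 and than in the cDNA line by 0.14, where 20 of 22 were higher. These signs held under median-of-ratios scaling. Mitochondrially encoded genes were all 13 higher than in the cDNA line, by a median of 0.30. The T-cell list had a median of -0.12 from wild type and -0.04 from the cDNA line. The small median against wild type hides large differences both ways, from -4.30 to 2.20. Of its 27 genes, 6 were at least 2-fold lower than in wild type and 2 at least 2-fold higher, and the cDNA line had the same counts against wild type.

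The 81 genes of this comparison were not more than simulated unchanged lines gave. Each spread used may include real differences between lines, so the simulated counts can be too high. The lack of an excess therefore does not show that a shared library alone explains the 81. Unchanged lines simulated against 1 shared library, with the spread seen between the derived lines, gave 43.6 higher and 52.9 lower. With the larger spread between the cDNA line and wild type they gave 145 and 135. Independent lists of these sizes would share 3.17 and 3.35 genes. The covariance of the 2 differences was 0.0604, against 0.0631 and 0.133 in the simulations, and r across genes was 0.33 against 0.50 in both.

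Without asparagine, 118 genes were at least 2-fold higher in the knockout-labelled library than in both other lines and 49 lower. Under median-of-ratios scaling the counts were 70 and 58. The transcription factor genes JUN and PAX6 were among the higher, at 19.86 TPM against 4.73 in wild type and 6.33 in the cDNA line, and at 38.81 against 12.77 and 9.1. RNF170 was at 53.99 against 17.22 and 19.23 TPM, FAM184A at 40.04 against 10.98 and 15.68, and CNPY1 at 39.12 against 3.37 and 11.01. The chaperone gene HSPA8, one of the most abundant transcripts, was at 691.77 TPM against 2953.71 and 2076.78, and HSPA1B was at 8.1 against 40.21 and 30.06. The surface glycoprotein gene CD52 was at 1.82 against 11.91 and 8.28, KRT1 at 2.31 against 10.5 and 9.11, ATP6V0A1 at 1.35 against 22.82 and 5.85, and SNORD17 at 2.71 against 9.4 and 13.73. The pseudogenes WHAMMP1, SEPT14P3 and RPS28P7, and LUZP6, FAM27B and HSPA1B, which overlap or have near copies, are uncertain.

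ATF4 genes were higher in the knockout-labelled library without asparagine, by a median of 0.74 over wild type and 0.52 over the cDNA line (0.59 and 0.36 under median-of-ratios scaling). ATF3 stood at 48.08 TPM against 16.77 and 22.11, TRIB3 at 838.88 against 315.31 and 430.68, and CEBPB at 78.56 against 44.45 and 46.11. Ribosomal protein genes were lower, with a median of -0.26 against wild type and -0.21 against the cDNA line, in the library where they took the smallest share of TPM (-0.42 and -0.37 under that scaling). Cholesterol genes differed from the cDNA line by -0.16 and from wild type by -0.01, or by -0.32 and -0.15 under that scaling. The median gene was itself 0.17 above wild type and 0.16 above the cDNA line.

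Beside the 118 and 49, simulated unchanged lines sharing 1 library gave 45.1 and 60.7 with the spread between the derived lines, or 130 and 118 with the spread between the cDNA line and wild type. Independent lists would share 14.0 and 2.31 genes. The covariance was 0.128, against 0.0890 and 0.120 simulated, and r was 0.54 against 0.50 in both. The 49 lower genes lay within the 47.5 to 76 simulated with the smaller spread and below the 101 to 146 with the larger. The 118 higher lay above the 35 to 58 simulated with the smaller spread and within the 107 to 157 with the larger. The simulations hold no shift of all genes, while the median gene lay 0.17 above wild type and 0.16 above the cDNA line. Under median-of-ratios scaling, which centres the libraries, 70 were higher and 58 lower, with no simulation at that scaling. An excess thus appeared only for the higher genes against the smaller spread, and part of it may come from that shift or the shared library. In both media, 5 genes were at least 2-fold lower than in both other lines (ASNS, ATP6V0A1, KRT1, CCNI2 and EIF3CL). The 5 higher in both were TSHR, SEPT14P3 and the unnamed ENSG00000251550, ENSG00000270048 and ENSG00000274944. CCNI2, EIF3CL and the unnamed genes were named after their values were seen.

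The response to withdrawal differed at least 2-fold from both other lines for 195 genes in the upward direction and 63 in the downward direction in the knockout-labelled line, or 140 and 85 under median-of-ratios scaling. The same count was 57 and 135 for wild type against the other lines and 84 and 92 for the cDNA line. HSPA8 went from 2022.27 to 691.77 TPM in that line, and from 2791.22 to 2953.71 in wild type and 2194.69 to 2076.78 in the cDNA line. HSPA1B went from 33.62 to 8.1 TPM in the knockout-labelled line, and its near copies make it uncertain. GRIP1 went from 16.06 to 2.03 TPM and ERP27, an endoplasmic reticulum protein gene, from 8.42 to 2.58, while wild type had 6.28 to 6.38 and 7.89 to 7. The genes named for a higher response were LUZP6, SEPT14P2, HIST2H2AA3, SNRPGP10, RNF185-AS1, RMRP, USP41 and WHAMMP1. RMRP, like SNORD17 above, is one of the small noncoding RNA genes left out in the rescaling without such genes. Its level with asparagine varied widely between lines. It went from 38.08 to 58.48 TPM in the knockout-labelled line, 71.29 to 35.99 in wild type and 166.53 to 49.58 in the cDNA line. The others are pseudogenes, antisense or overlapping genes, or members of near-identical families, and are uncertain. So are RPS28P7, RPL23AP42, FAM27B and FOXP4-AS1 among those with a lower response.

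By group, the response of the cholesterol genes was lower in the knockout-labelled line than in wild type by a median of -0.81 and than in the cDNA line by -0.37. These genes lay a median of 0.77 above wild type with asparagine and differed from it by -0.01 without. The difference from wild type thus lay mainly in the level with asparagine. From the cDNA line they differed by 0.14 with asparagine and -0.16 without. The response of the ATF4 genes was higher by 0.45 and 0.38. JUN and ATF3 led the immediate early and ATF4 lists, at 1.76 and 2.24 above wild type and 1.38 and 1.36 above the cDNA line. Synthetases differed by 0.27 and 0.25. Under median-of-ratios scaling the ATF4 values were 0.26 and 0.25 and the synthetase values 0.07 and 0.11, and the cholesterol genes kept their direction. Carriers differed from wild type by 0.19, a value that turned to -0.0043 under that scaling. Mitochondrially encoded genes differed by -0.25 and -0.51, or by -0.45 and -0.65 under that scaling. Simulated unchanged lines that share 1 line gave 101 higher and 92.5 lower responses, against the 195 and 63, and independent lists would share 15.9 and 2.50 genes. The covariance was 0.147, against 0.119 simulated. Only the higher responses were in excess, and part of that may come from the shared line or from a shift of all genes, which the simulation leaves out. Under median-of-ratios scaling the observed counts were 140 and 85, with no simulation at that scaling. The libraries of the knockout-labelled line enter all of these, and with 1 library per group no test of a differing response could be made.

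Responses of the 3 lines were related across genes, which are not independent replicates. Pearson r over 14326 genes was 0.38 between wild type and the knockout-labelled line, 0.29 between wild type and the cDNA line, and 0.47 between the derived lines. Spearman rho was 0.52, 0.45 and 0.57 in the same order. The paired responses within each comparison share no library, while each line enters 2 of the 3 comparisons. No p is given, since genes such as those of cholesterol synthesis move together.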

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

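In this part the test of median-of-ratios scaling and that of response against gene length had bounds set before the result was seen, and the remaining tests were chosen after it was seen.

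Of the genes named in the text, 7 had a response beyond 1.5-fold one way in one line and beyond it the other way in another, with 1 library each, and these differences were not tested. PRSS2 had responses of 0.81 in wild type, -0.76 in the knockout-labelled line and 0.22 in the cDNA line. SEPT14P2 had 0.04, 4.29 and -4.28, and was listed at 0 in 2 libraries. LUZP6 had -6.10, 5.06 and 0, and was listed at 0 in 4 libraries. WHAMMP1 had -0.59, 1.25 and -0.25. FAM27B had -1.63, -4.51 and 1.14, and HIST2H2AA3 had -3.35, 1.26 and -1.16, each listed at 0 in 1 library. RMRP had -0.97, 0.61 and -1.73. Where a library was listed at 0, the size of the response is set by the pseudocount and is no measured fold.

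In the knockout-labelled line 79.3% of the genes at least 2-fold different after withdrawal were higher, against 45.1% in wild type and 58.3% in the cDNA line. A lower share of ribosomal protein, mitochondrial, histone and small noncoding RNA is argued against as the whole cause, since 68.8% were higher after rescaling without them, against at most 52.2% in the other lines. Longer genes among those higher are argued against, since their median length was 26.98 kb, within the 22.9 to 30.5 kb of random lists, for the 84.9% with a length; whether length bears on the split stays open, as the lower genes had a median of 10.7 kb (random lists 16.7 to 30.3 kb) in a check that is void with a length for only 71.0%, and rho of response with length was 0.10, between the bounds set beforehand (0.07 in wild type, -0.02 in the cDNA line). A broader drop in abundant RNA cannot be told apart from a true broad increase: under median-of-ratios scaling 57.6% were higher, against at most 50.8% in the others, but that scaling centres each library and so removes a broad shift of either origin. An effect of ZBTB1 loss stays open and untested, as 1 library carries the pattern.

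The 934 genes at least 2-fold different in the knockout-labelled line may be a larger form of a response that the other lines also make. For the medians and shares here, the median response of all genes in a line was first subtracted from its responses. Genes were chosen on values without that step. The median response of the 934 in the same direction was 0.38 in wild type and 0.52 in the cDNA line. Both lay above the central 95% of random lists, whose upper ends were 0.0057 and 0.025. In those lines 80.6% and 82.5% moved the same way. Genes chosen in the cDNA line (391) had a median of 0.59 in the knockout-labelled line against 0.30 in wild type, and genes chosen in wild type (257) had 0.53 against 0.28 in the cDNA line. Why the size differed was not tested, and neither a longer or harsher withdrawal in that culture nor an effect of genotype can be separated with 1 library.

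ASNS was lower in the knockout-labelled line than in both other lines in both media. A difference carried by the knockout clone into every line made from it is argued against as the whole cause, since the cDNA line lay 12.9 and 5.69 robust SD of like-expression genes above the knockout-labelled line with and without asparagine. The cDNA line stayed below wild type by 1.64-fold, so a part carried by the clone remains possible. An exchange of the knockout and cDNA labels cannot be told apart: ZBTB1 was higher in the cDNA line by 2.81 robust SD with asparagine but by 1.52 without, and whether the TPM values count transcripts of the cDNA is not given in the sources used here. The design names ZBTB1 as a biological explanation, which stays open because no second knockout line enters these data.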

How the results depend on the processing

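The alternatives here were planned, and the count of splits was chosen after the result was seen. No counting depth is known for TPM, which limits low genes most. Methods that need counts (edgeR, DESeq2, size factors and whole reads recovered) were not run, since TPM keeps no counts. Over the results that answer a comparison, 69 values stayed within their spread or within 1.5 times the main count and 61 moved further. None was labelled reversed, but counts and correlations could not be, and single genes only where the main difference reached 2-fold. The absence of reversals is thus no sign of stability. The balance of higher and lower genes did turn in some settings, given below. Of 266 values of named genes, 242 kept their direction and side of the 2-fold line, 24 moved across it and 0 reversed. Of 145 medians of the cholesterol, ATF4, synthetase, carrier and ribosomal protein lists, 144 moved by less than the spread of single genes of like expression, a wide bound that a shift of all genes hardly exceeds. Within it the synthetase difference between the knockout-labelled line and wild type went from 0.27 to 0.07 under median-of-ratios scaling. The difference of amino acid carriers between the knockout-labelled line and wild type went from 0.19 to -0.0043 under median-of-ratios scaling, by its construction a shift of all genes. Where no reason follows from the setting itself, the cause was not tested.

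Genes at least 2-fold different in all 3 lines numbered 38, which became 101 with a pseudocount of 0.1, 16 with 5, 22 with a mean of at least 10 TPM, 252 at 1.5-fold and 9 at 3-fold. The 21 higher and 17 lower became 19 and 21 under median-of-ratios scaling, 6 and 10 with a pseudocount of 5, 7 and 15 at a mean of at least 10 TPM, and 8 and 1 at 3-fold. Leaving out a line gave 59 to 143: 143 without wild type, 59 without the knockout-labelled line and 86 without the cDNA line. With a pseudocount of 0.1 the single-line counts were 588 in wild type (from 257), 1515 in the knockout-labelled line (from 934) and 842 in the cDNA line (from 391). With 5 they were 64, 292 and 91, at a mean of at least 10 TPM 54, 372 and 87, at 1.5-fold 994, 3467 and 1723, and at 3-fold 78, 202 and 116. In wild type 116 higher and 141 lower became 21 and 43 with 5, and 16 and 38 at a mean of at least 10 TPM. In the cDNA line 228 and 163 became 198 and 192 under median-of-ratios scaling and 45 and 46 with 5. Without a filter wild type had 440 and the cDNA line 702.

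Genes differing in the knockout-labelled line from both others numbered 81 with asparagine, 167 without and 258 for the response. A pseudocount of 0.1 gave 234, 370 and 539, and 5 gave 17, 29 and 44. No filter gave 164, 290 and 465, and a mean of at least 10 TPM 14, 30 and 40. Thresholds of 1.5-fold gave 338, 1016 and 1101, and 3-fold 24, 34 and 70. With asparagine the 36 higher and 45 lower became 102 and 62 without a filter and 10 and 7 with a pseudocount of 5, and without asparagine the 118 and 49 became 859 and 157 at 1.5-fold. ASNS in the knockout-labelled line against the cDNA line with asparagine went from -1.71 to -1.56 with a pseudocount of 5. The correlation between wild type and the knockout-labelled line was 0.26 with a pseudocount of 0.1, 0.51 with 5 and 0.48 at a mean of at least 10 TPM. That between wild type and the cDNA line was 0.16, 0.44 and 0.45, and that between the derived lines 0.32, 0.61 and 0.67, with 0.35 without a filter.

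The 1377 limma calls became 0 without a filter (4348 at an unadjusted p below 0.05) and 0 with a constant prior (3753), where the smallest adjusted p was 0.201 and 0.0879. Without line as a replicate block there were 7, and 149 remained with a 2-fold threshold added. Leaving out a line gave 282 to 770: 282 without the knockout-labelled line (268 of them among the 1377), 524 without the cDNA line and 770 without wild type. Median-of-ratios scaling gave 1612 calls, 1244 of them shared. Among the 10 splits of the 6 libraries into 3 and 3, the real split alone (1 of 10) gave as many calls, and the highest other gave 1. Most of the other splits part the libraries of only 1 line. With line as a block their effect rests on 1 pair, which makes them a weak comparison. So few splits cannot give a share under 0.05.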

Other observations

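All groups and tests in this part were chosen after values were seen.

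Most heat-shock genes examined were lower in the knockout-labelled line after asparagine withdrawal. For 14 heat-shock and chaperone genes, picked once HSPA8 and HSPA1B had appeared among the named genes, the median response was -0.62 there, with 11 of 14 below 0. It was -0.14 in wild type, with 9 of 14 below 0, and -0.05 in the cDNA line, with 10 of 14 below 0. HSP90AB1, a cytosolic chaperone gene, went from 1227.94 to 593.74 TPM in the knockout-labelled line and from 1810.61 to 1481.64 in wild type, and DNAJB1 from 117.6 to 54.93 and from 141.32 to 118.82. The mitochondrial chaperone gene HSPA9 went the other way in all 3 lines, from 245.18 to 454.54 in the knockout-labelled line, as did HSPA4 (154.27 to 192.13), and HSPB1 was at 115.99 and 120.61 there. Without HSPA8, HSPA1B and its near copy HSPA1A, the medians of the other 11 genes were -0.62 in the knockout-labelled line and -0.22 in wild type, both below the central 95% of 10000 random lists matched on expression, and -0.02 in the cDNA line, within it.

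Wild type differed from both derived lines in a set of genes in both media. At least 2-fold differences from both derived lines in both media were found for 123 genes higher in the derived lines and 100 lower, where simulated unchanged lines, with the spread between the derived lines, gave 6.67 and 4.52. The adhesion receptor gene CD2 was at 30.07 TPM in wild type with asparagine, 0.58 in the knockout-labelled line and 0.35 in the cDNA line. ANXA1 was at 167.63, 8.4 and 11.07 TPM, and the T-cell receptor constant gene TRAC at 40.52, 2.71 and 6. Higher in the derived lines were the T-lineage transcription factor gene TCF7 (59.98, 278.82 and 244.26 TPM), CHI3L2 (71.87, 559.1 and 568.01), LGALS1 (26.2, 158.85 and 174.93) and CD1A (1.89, 11.84 and 17.41).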
